A study of Homo sapiens with 20 samples.

How the data were processed

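Messenger RNA was measured in 20 libraries of the established human breast cancer lines MCF-7 and LCC9, in 4 groups of 5: each line with DMSO and each with 100 nM 4-OHT. Per the labels' protocols, MCF-7 was maintained with 10% serum and LCC9 with 5%, so the routine serum level differed between the lines. All cells then spent 72 h in phenol red free medium with 5% charcoal-stripped serum, which removes steroid hormones, before 24 h of treatment. Polyadenylated RNA was prepared with an Illumina stranded mRNA kit from 50 ng of input, per the labels' protocols. Selection of polyadenylated RNA leaves most replication-dependent histone transcripts poorly captured.

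The values are raw counts per gene, whole numbers with no scaling, in a table deposited by the authors with a column for each library. The submitters' processing notes name FastQC, STAR 2.6, HTSeq 0.10.0 and the hg38 build, without the order of the steps. The strand setting of the counting and the release of the gene annotation are not given in the sources used here, so values of antisense and overlapping genes are uncertain. Reads of near-identical paralogs can be split or lost by such counting. The table held 44452 gene identifiers. A reference table of gene names gave a symbol for 34022 of them, and 44392 were found in GENCODE release 29 for hg38, from which all coordinates, biotypes and transcript lengths come. The other 60 were kept in the tests without coordinates. Genes of the mitochondrial chromosome had 0 identifiers in the table, so a list of mitochondrially encoded transcripts was not analysed here, nor was a list of ribosomal protein genes, whose members had no identifier in it.

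Total counts were 33.5, 30.7, 32.8, 31 and 27.8 M (M, 1e6 counts) in MCF-7 DMSO replicates 1 to 5 and 29.7, 30, 31.9, 29 and 29.7 M in MCF-7 4-OHT. They were 28.4, 26.4, 32.4, 36.4 and 30.5 M in LCC9 DMSO and 27.7, 31.7, 30.9, 28.9 and 30.2 M in LCC9 4-OHT. At this depth a floor of 3 counts over the 5 libraries of a group stood for genes without counts, and a fold against such a group was computed against the floor and given as a lower bound. Libraries of a group were checked for duplicates by comparing their counts over genes. The closest pair, MCF-7 DMSO replicates 3 and 4, had a median variance between them of 1.93 times counting noise. None was therefore taken for a copy, and each library counted as 1 replicate. This check cannot show that libraries came from separate cultures.

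Groups and replicate numbers were taken from the sample titles. Genes were kept by edgeR's expression filter (minimum count 10, minimum total 15), which left 17131 genes with 99.95% of all counts. Libraries were scaled by TMM factors, and a quasi-likelihood model with a mean for each of the 4 groups was fitted in edgeR 4.0.16 (R 4.3.3). It shared 1 estimate of the spread over all 20 libraries, with 16 residual degrees of freedom and a common biological coefficient of variation of 0.204. The 5 contrasts were the lines in DMSO, the lines in 4-OHT, the drug in MCF-7, the drug in LCC9, and the difference of the drug effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold threshold. Per-library levels are CPM from TMM-scaled library sizes, and log2 CPM used a prior count of 2.

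The groups, contrasts, tests, 28 gene lists, the rule for named genes and most alternatives were set before the data were examined. The lists had 702 entries, of which 629 were found in the table. Each list with at least 3 tested members was compared with the other genes by camera (limma 3.58.1, two-sided, preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison). Of 130 such tests, 26 per comparison, 31 were called, and 8 were called with an estimated correlation. 14 of the lists were called in no comparison. Counts of list members were adjusted over all genes and over the list alone.

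Named genes were, per contrast, the 10 with the highest and the 10 with the lowest fold change among called genes that moved the same way in all 25 pairs of libraries and had a mean count of at least 10 in each group. For the lines in 4-OHT these were 5 and 5, and for the difference of drug effects 6 and 6 without the pairs condition. In addition came the 3 most abundant genes in each direction with no count in a whole group, up to 4 members of each list with the smallest adjusted p, every member of the m6A list, and ESR1, PGR, TFF1 and GREB1 everywhere. Clone-based and placeholder names, pseudogenes and Y-linked genes were passed over, and 1 gene that the rule names is not reported here. Of the list members so given, those printed were chosen after their values were seen.

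The overlap of calls was compared with the product of the call rates and tested by Fisher's exact test. The covariance of the baseline line difference and the drug effect in MCF-7 was taken over all 10 ways of dividing the MCF-7 DMSO libraries between the contrasts, beside 20 simulations of unchanged groups. The procedure was tested on simulated draws from each gene's mean over all libraries, its spread and library sizes, with 200 of 17131 genes changed. At simulated log2 changes of 0.5, 1 and 2 it recovered 23.5, 71.4 and 94.5% of changed genes for the lines in DMSO and 22.7, 69.4 and 98.1% for the lines in 4-OHT. Recovery was 18.6, 68.2 and 92% for the drug in MCF-7, 26.8, 71.4 and 94.6% for the drug in LCC9, and 4.48, 57.1 and 88.9% for the difference. False calls made up 5.38, 1.65, 3.85, 3.57 and 1.98% of the calls, in that order of comparisons. Libraries were drawn independently, with none set apart from its group and no trend on transcript length, so these shares need not hold in the real data.

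Alternatives changed 1 choice at a time: scaling (DESeq2 size factors, or library sizes alone), the low-count filter (none, or 1 CPM in 5 libraries), a block on replicate number, each library left out, DESeq2 1.42.0 in place of edgeR (genes it gave no adjusted p for were kept out of the counts), a fold threshold of 2, an adjusted p under 0.01, only the libraries of the groups compared, and a robust estimate of the spread. For lists, an estimated correlation and fry replaced camera. Fits without the 3 MCF-7 libraries that stand apart, each with over 500 of the well-expressed genes at least 2-fold off its group's median, and fits with each library's trend on transcript length removed (lowess span 0.3) were added after the data were seen. Transcript length and GC content are those of a gene's longest transcript in GENCODE release 29. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for annotation and plots.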

Results

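The series measured mRNA abundance by sequencing in a pair of established human breast cancer cell lines. MCF-7 is an estrogen receptor positive line that depends on estrogen signalling for growth, and LCC9 is a derivative of MCF-7 that the labels describe as resistant to tamoxifen. Cells were kept for 72 h in hormone-depleted medium and then received either the solvent DMSO or 100 nM 4-hydroxytamoxifen (4-OHT), the active metabolite of the antiestrogen tamoxifen, for 24 h. Crossing line and treatment gave 4 groups of 5 libraries: MCF-7 DMSO, MCF-7 4-OHT, LCC9 DMSO and LCC9 4-OHT. Total gene counts ran from 26.4 M to 36.4 M (M, 1e6 counts) per library, with a median of 30.3 M. Of the 44452 genes in the table, 17131 carried enough counts to be tested. Levels below are CPM, a gene's count per 1e6 counts of its scaled library, given as mean ± SD over the 5 libraries of a group. Fold changes are fitted log2 values ± SE, and p-values come from edgeR's quasi-likelihood test, adjusted by the Benjamini-Hochberg method. The labels do not say whether the 5 libraries of a group came from separate cultures, so these p-values measure only the spread between the libraries, which may be technical.

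Cell line was the main axis of variation. Over the 2000 most variable genes the first principal component held 92.2% of the variance and placed the LCC9 libraries between 88 and 93.3 and the MCF-7 libraries between -100 and -58.5. Treatment separated the remaining MCF-7 libraries along lower components, where 3 of them stood apart from their groups. Replicate 2 of MCF-7 DMSO had 658 of 10241 well-expressed genes at least 2-fold off its group's median. Replicate 5 of MCF-7 DMSO had 766 and replicate 5 of MCF-7 4-OHT had 525, while no other library had more than 20. Replicate 5 of MCF-7 DMSO lay at 64.2 on the second component. It held 947 CPM of GREB1, an estrogen-induced regulator of the estrogen receptor, where the other 4 libraries of its group held 85.3 to 202. The number of genes called in each comparison is therefore also given without these 3 libraries, an alternative chosen after the data were seen. Pairs within a group that hold 1 of these libraries varied at 22 to 53.2 times counting noise, other such MCF-7 pairs at 1.93 to 5 times. Leaving the 3 out thus removes most of the spread between MCF-7 libraries, which can raise the number of calls by itself.

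**Figure D1:**
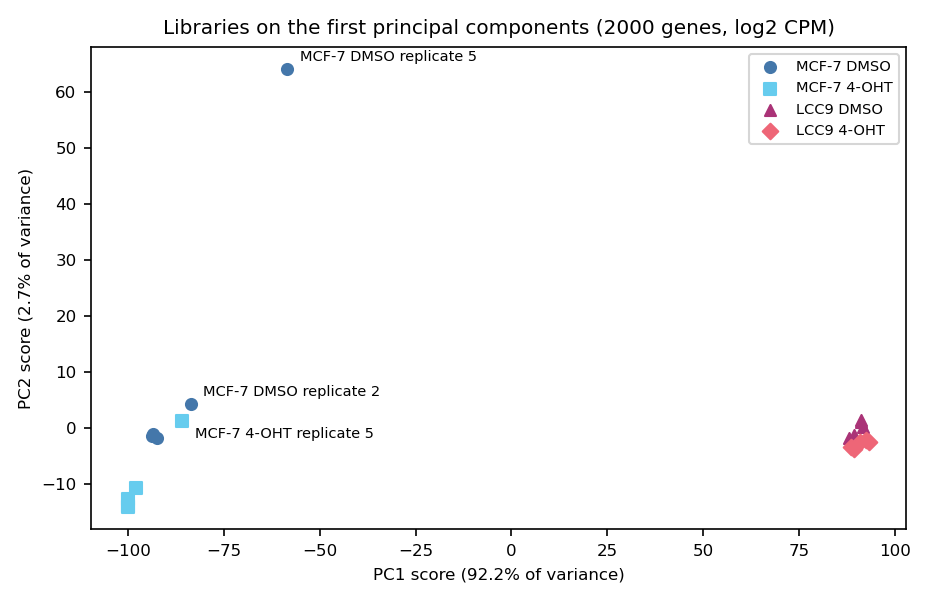
Each point is 1 of the 20 libraries, placed by its scores on the first (horizontal) and the second (vertical) principal component of log2 CPM over 2000 genes; colour and shape mark the 4 groups. LCC9 libraries lie between 88 and 93.3 on the first component, and MCF-7 DMSO replicate 5 lies at 64.2 on the second.

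The comparison of LCC9 with MCF-7 in DMSO asked how the resistant line differed from its parent without drug. LCC9 held more mRNA of most interferon-stimulated genes (34 of 41 tested), and far more of the growth factor amphiregulin and of several genes that MCF-7 hardly transcribed. It held far less mRNA of the matrix gene HMCN1, of galectin-3 and of a pair of protocadherins. BST2, an interferon-induced membrane protein that tethers virus particles, stood at 3.09 ± 1.42 CPM in MCF-7 and 527 ± 105 in LCC9 (log2 7.43 ± 0.28, adjusted p = 1.14e-14; chromosome 19, 17402939 to 17405648). AREG, which encodes the EGF receptor ligand amphiregulin, rose from 3.17 ± 6.21 to 347 ± 23.6 CPM (log2 6.83 ± 0.83; chromosome 4, 74445134 to 74455009). HMCN1, a large extracellular matrix protein, fell from 302 ± 163 to 0.427 ± 0.172 CPM (log2 -9.42 ± 0.51; chromosome 1, 185734551 to 186190949), and LGALS3, the lectin galectin-3, fell from 543 ± 119 to 3.43 ± 0.42 CPM (log2 -7.30 ± 0.18; chromosome 14, 55124110 to 55145413).

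Among genes with a mean count of at least 10 in each group, the 10 with the highest fold change in LCC9 were TM4SF18-AS1 (log2 9.06), the epithelial transcription factor EHF (7.47), BST2, AFAP1L2 (7.20), AREG, the serine protease HPN (6.62), TEX19 (6.53), the peptidylarginine deiminase PADI3 (6.24), the prostaglandin-degrading enzyme HPGD (6.2) and HOXC10 (6.18). The largest adjusted p among them was 4.14e-07. The strand setting of the counting is not given in the sources used here, so the antisense gene TM4SF18-AS1 could hold reads of its overlapping partner. The 10 lowest were HMCN1, the protocadherins PCDH10 (-8.32) and PCDH7 (-7.78), the potassium channel KCNJ8 (-7.43), the heparan sulfatase SULF1 (-7.41), the cell cycle kinase CDK6 (-7.40), LGALS3, FLRT3 (-6.99), caveolin CAV1 (-6.96) and CLEC3A (-6.90), with a largest adjusted p of 1.71e-10. Some genes had no count in any of the 5 libraries of a line. Set against a floor of 3 counts over the 5 libraries of a group, SAGE1 (55.3 ± 5.80 CPM), PIP (25.8 ± 6.24) and RASGRF1 (20.8 ± 5.27) were at least 2820-fold, 1320-fold and 1060-fold higher in LCC9. TMEM26 (17.7 ± 7.70 CPM in MCF-7), PLCXD3 (15.2 ± 27.4) and PLPPR5 (7.27 ± 1.07) were at least 938-fold, 803-fold and 385-fold lower there. Floors and CPM cover counting error only. Without MCF-7 DMSO replicate 5 the log2 changes were 9.79 for AREG, 10.87 for TM4SF18-AS1 and 8.10 for PADI3. PLCXD3 held 64.1 CPM in that library and at most 3.52 in the others, and its fitted change moved to -9.49.

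In all, 12706 of 17131 genes (74.2%) differed, 6237 higher and 6469 lower in LCC9, and 14243 without the 3 libraries that stand apart (7239 higher, 7004 lower). The median absolute log2 change of the called genes was 1.03, and across genes the fold change had a correlation of -0.374 with log2 transcript length. Of the interferon-stimulated genes, 34 of 41 rose and 2 fell (34 and 3 adjusted over the list alone). The list stood above the other genes by camera at adjusted p = 2.06e-09 with the preset correlation of 0.01, and adjusted p = 0.32 with an estimated correlation. Its members with the smallest p included the RNA helicase relative DDX60 (log2 5.08), IFI27 (4.60) and the ADP-ribosyltransferase PARP9 (2.04). Genes of antigen presentation by MHC class I went mostly the same way, with 11 of 16 higher and 3 lower (12 and 3 adjusted over the list alone). The peptidase ERAP2 (3.84) and HLA-F (2.92) rose, but TAPBP, the tapasin gene, fell (-1.15). That list was not called (adjusted p = 0.0919), and its adjusted p was 0.0491 without the 3 libraries. Of 36 nuclear-encoded respiratory chain genes, 32 rose and 0 fell (32 and 0 adjusted over the list alone), with adjusted p = 0.00229 and adjusted p = 0.853 with an estimated correlation. Examples were the complex I subunit NDUFV2 (log2 1.97), the complex II subunit SDHC (0.69) and the mitochondrial transcription factor TFAM (1.32).

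Receptors and lineage markers differed in both directions. ESR1, which encodes estrogen receptor alpha, fell from 413 ± 126 to 127 ± 23.3 CPM in LCC9 (log2 -1.71 ± 0.18, adjusted p = 4.86e-08; chromosome 6, 151656691 to 152129619). Its target TFF1 rose from 485 ± 225 to 2160 ± 407 CPM (2.16 ± 0.29, adjusted p = 1.75e-06; chromosome 21, 42362282 to 42366594). The change of PGR, the progesterone receptor gene, was -0.62 ± 0.34 (adjusted p = 0.103) and became -0.84 (adjusted p = 0.0116) without MCF-7 DMSO replicate 2. Over all single libraries left out it ranged from -0.84 to -0.06, with adjusted p up to 0.837 by edgeR. The change of GREB1 was 0.67 ± 0.42 (adjusted p = 0.154) and became 1.63 (adjusted p = 1.76e-06) without replicate 5. Of 36 estrogen receptor target genes 14 were higher and 8 lower (the same counts adjusted over the list alone). Among them the adenosine receptor ADORA1 (log2 3.67) was higher, and the corepressor NRIP1 (-1.78) and the protease CTSD (-1.46) were lower. That list was not called (adjusted p = 0.396), but it stood higher at adjusted p = 0.000501 without the 3 libraries, with 26 genes higher and 7 lower. Luminal epithelial markers had 5 of 22 higher and 10 lower in both adjustments, among the latter AGR2 (-4.01), the transcription factor GATA3 (-1.62) and the mucin MUC1 (-1.70). The list had adjusted p = 0.177, and 0.0161 with the transcript length trend removed. Basal and mesenchymal markers split, with 7 of 18 higher and 11 lower (adjusted p = 0.387). The intermediate filament vimentin, VIM, rose from 0.305 ± 0.119 to 50.1 ± 3.81 CPM, and the matrix protein TGFBI fell by 4.89 on the log2 scale. Of the receptor tyrosine kinases and ligands, FGFR4 rose (5.01) and FGFR2 fell (-3.13), and the list was called in no comparison (smallest adjusted p = 0.706).

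**Figure D2:**
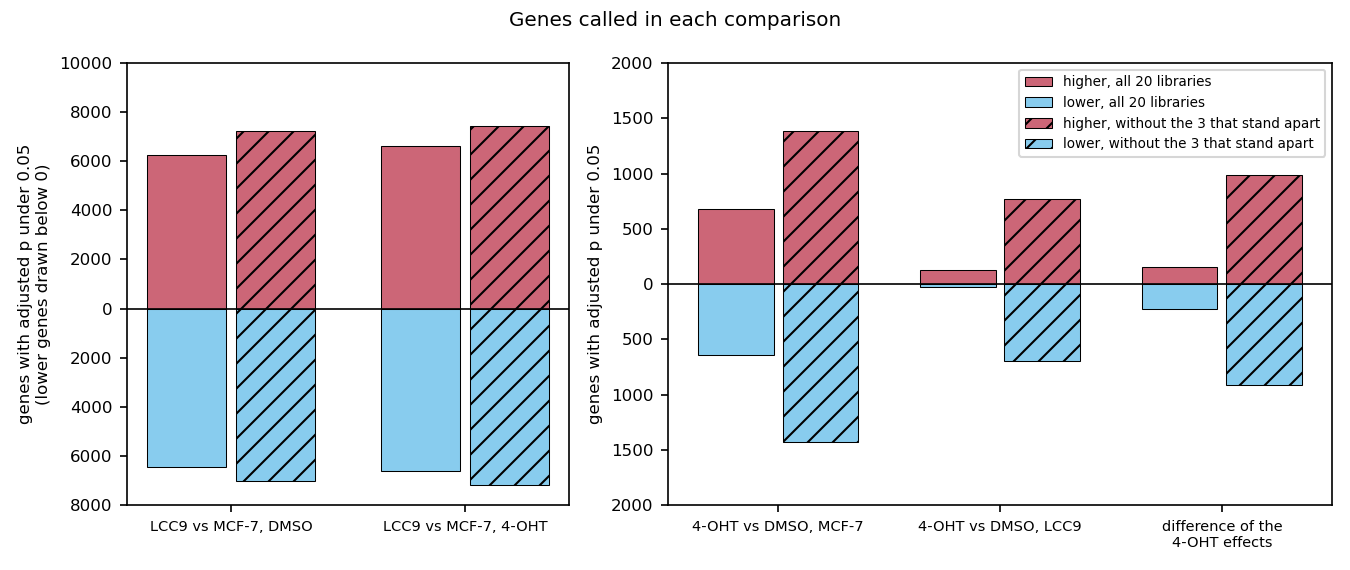
Bars give the number of genes past an adjusted p of 0.05 in each comparison, higher genes above 0 and lower genes below 0, with all 20 libraries (plain) and without the 3 MCF-7 libraries that stand apart (hatched); the vertical scales of the left and right panels differ. The 4-OHT comparison in LCC9 went from 161 to 1464 genes without them.

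The same comparison in 4-OHT asked which line differences were present under drug. The estrogen-induced TFF1 and GREB1 were far higher in LCC9: TFF1 stood at 106 ± 49.8 CPM in treated MCF-7 and 3320 ± 775 in treated LCC9 (log2 4.97 ± 0.33, adjusted p = 5.56e-11), and GREB1 at 17.7 ± 1.88 and 716 ± 156 CPM (5.34 ± 0.50, adjusted p = 8.47e-09; chromosome 2, 11482341 to 11642788). PGR was higher as well (1.22 ± 0.34, adjusted p = 0.00311), and ESR1 remained lower (-1.46 ± 0.18, adjusted p = 3.16e-07). CCN2, a secreted matricellular protein, was much lower in LCC9, at 0.65 ± 0.173 against 124 ± 54.5 CPM (-7.56 ± 0.43). In all, 13233 genes differed (77.2%), 6638 higher and 6595 lower, with a median absolute log2 change of 1.11. The count was 14588 without the 3 libraries (7416 higher, 7172 lower). Across genes the fold change had a correlation of -0.362 with log2 transcript length, and scaling by library size alone moved the median over all genes by 0.11 on the log2 scale.

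Among genes with a mean count of at least 10 in each group, the 5 with the highest change were AREG (log2 9.34), BST2 (8.04), EHF (7.74), TEX19 (7.55) and HPGD (7.14), and the 5 lowest were PCDH10 (-9.18), CLEC3A (-8.85), CDK6 (-8.12), CCN2 and FLRT3 (-7.10). Against the floor, SAGE1, CT45A10 and the cytokine IL19 were at least 2910-fold, 1030-fold and 581-fold higher in LCC9, and ARMCX1, TMEM26 and BTNL9 at least 1740-fold, 1310-fold and 890-fold lower. Between the treatments, 5752 genes were higher in LCC9 both times, where independent lists would share 2420, and 5899 were lower both times, where they would share 2490. Only 32 and 16 genes changed sides. The line effects had a correlation of 0.955 across the tested genes, which are not independent replicates.

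By list, interferon-stimulated genes were again higher in LCC9, with 35 of 41 up and 1 down in both adjustments (adjusted p = 2.15e-08, and adjusted p = 0.391 with an estimated correlation), for instance IFI27 (log2 5.37). Estrogen receptor targets had 20 of 36 higher and 6 lower, also adjusted over the list alone (adjusted p = 0.0213, and adjusted p = 0.757 with an estimated correlation). Genes of DNA replication and G1/S had 26 of 29 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.00157, and adjusted p = 0.757 with an estimated correlation), such as the helicase subunit MCM7 (1.16) and cyclin E1, CCNE1 (1.35). Respiratory chain genes had 32 of 36 higher and 2 lower (32 and 3 adjusted over the list alone; adjusted p = 0.000751, and adjusted p = 0.757 with an estimated correlation). Immediate early and AP-1 genes are the fast-induced transcription factors of the FOS, JUN and EGR families and their relatives. They had 3 of 24 higher and 18 lower in both adjustments (adjusted p = 4.07e-05, and adjusted p = 0.633 with an estimated correlation), for example KLF4 (-4.96), the phosphatase DUSP4 (-4.68) and JUN (-2.76). Luminal markers had 5 of 22 higher and 13 lower (adjusted p = 0.0162, and adjusted p = 0.115 with an estimated correlation), with ELF3 at -2.70. Aryl hydrocarbon receptor and xenobiotic genes had 2 of 18 higher and 13 lower (adjusted p = 0.0125, and adjusted p = 0.115 with an estimated correlation), with the estrogen-hydroxylating CYP1B1 at -3.47. Replication-dependent histone genes had 12 of 23 lower and were not called (adjusted p = 0.152), nor were lysosome genes, with 4 of 26 higher and 14 lower (adjusted p = 0.105).

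In MCF-7, the comparison of 4-OHT with DMSO asked what the drug did to the parental line. Immediate early genes rose steeply, and the estrogen-induced genes GREB1 and TFF1 fell. FOSB went from 3.98 ± 0.555 to 719 ± 671 CPM (log2 7.50 ± 0.72, adjusted p = 5.68e-07; chromosome 19, 45467995 to 45475179), the orphan nuclear receptor NR4A1 from 17.9 ± 2.45 to 782 ± 314 (5.45 ± 0.35, adjusted p = 3.37e-09), and EGR1 from 66.5 ± 20.8 to 1740 ± 738 (4.71 ± 0.35, adjusted p = 1.52e-08). GREB1 fell from 321 ± 353 to 17.7 ± 1.88 CPM (-4.18 ± 0.47, adjusted p = 6.11e-06) and TFF1 from 485 ± 225 to 106 ± 49.8 (-2.19 ± 0.30, adjusted p = 4.96e-05). ESR1 changed by -0.30 ± 0.17 (adjusted p = 0.309) and PGR by -0.84 ± 0.34 (adjusted p = 0.137). Without the 3 libraries these were -0.62 (adjusted p = 0.00177) and -0.60 (adjusted p = 0.0483), and PGR was -1.07 (adjusted p = 0.027) without MCF-7 DMSO replicate 2 alone.

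**Figure D3:**
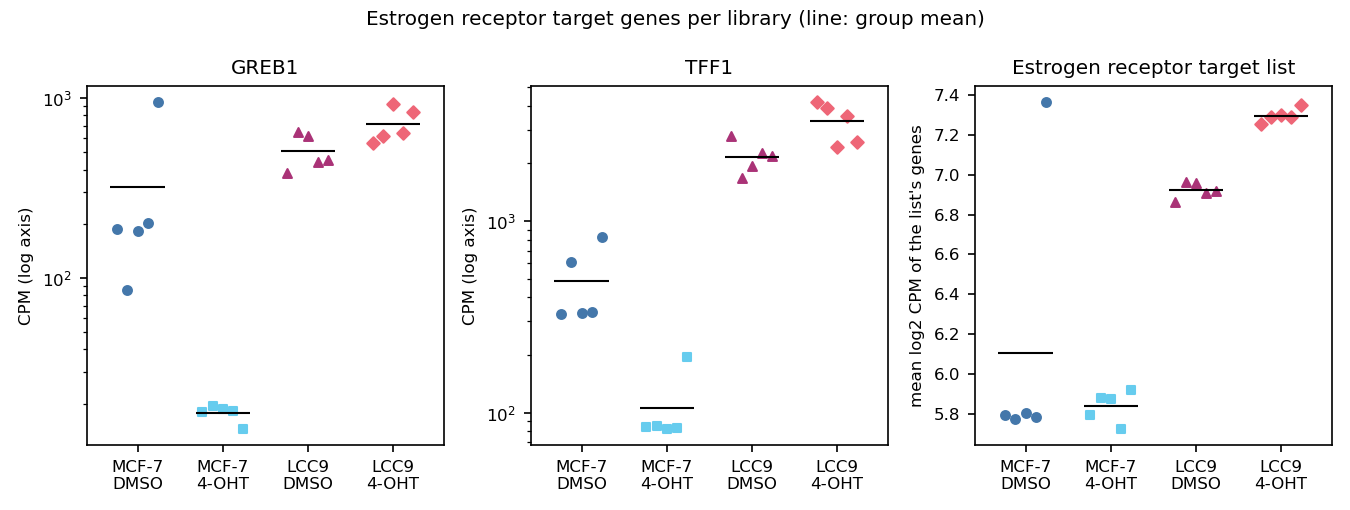
Points give each library's CPM of GREB1 and of TFF1 on log axes and, on the right, the mean log2 CPM of the 36 estrogen receptor target genes on a linear axis, by group; lines mark group means. GREB1 lay between 14.5 and 19.3 CPM in all 5 MCF-7 4-OHT libraries, and MCF-7 DMSO replicate 5 lay above its group in each panel.

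The 10 genes with the highest change also included EGR2 (log2 5.20), CCN2 (5.06), keratin 13, KRT13 (4.89), FOS (4.39), RASD1 (4.10), the Fc receptor FCGR2B (3.96) and the transglutaminase TGM2 (3.56), all with adjusted p of 7.94e-06 or less. The 10 lowest were GREB1, MAP1LC3B2 (-3.63), TNS4 (-2.37), TFF1, ASS1 (-2.10), FBLN2 (-2.08), RGS22 (-2.04), KREMEN2 (-2.01), CDCA7 (-1.84) and the transporter SLC22A4 (-1.83). Several of these falls were set by MCF-7 DMSO replicate 5. Without it the changes were -3.21 for GREB1, -0.80 for MAP1LC3B2, -1.21 for TNS4 and -0.45 for ASS1, each still past the threshold. ASS1 lost its call without any of MCF-7 4-OHT replicates 1 to 4 (adjusted p = 0.0569 to 0.0644). FOSB ranged from 51 to 1700 CPM among the treated libraries, and its change was 6.90 without replicate 3.

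Between the treatments 1315 genes differed in MCF-7 (7.68%), 676 higher and 639 lower with 4-OHT, with a median absolute log2 change of 0.739. Without the 3 libraries 2819 did (1389 up, 1430 down). A wrong split of the same libraries gave 2681 calls, so the count does not show that the drug made it. Handling shared by the treated cultures cannot be told apart from the drug either. Fitted on the 2 MCF-7 groups alone, the count was 360 (253 up, 107 down). With library sizes alone as scaling, 532 rose and 1015 fell. Across genes the fold change had a correlation of 0.304 with log2 transcript length. The count was 2804 without MCF-7 4-OHT replicate 5, and 805, 761, 786 and 875 without its replicates 1, 2, 3 and 4.

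Of the 24 immediate early and AP-1 genes, 19 rose and 0 fell (21 and 0 adjusted over the list alone), with adjusted p = 7.8e-59 by camera and adjusted p = 0.001 with an estimated correlation; besides those named, DUSP1 rose by log2 3.42. DNA replication and G1/S genes fell, 18 of 29 with 0 higher (28 and 0 adjusted over the list alone), with adjusted p = 6.03e-31, and adjusted p = 0.0627 with an estimated correlation. In MCF-7 4-OHT replicate 5 they had not fallen: the mean log2 CPM of the list was 5.56 there, against 4.11 to 4.15 in the other 4 treated libraries and 5.41 to 5.67 in DMSO. Without the 3 libraries all 29 fell. Members with the smallest p included the helicase subunits MCM2 (-1.12), MCM6 (-1.05) and MCM7 (-0.77). Mitosis genes as a list shifted down (median log2 -0.504, adjusted p = 1.35e-05, and adjusted p = 0.899 with an estimated correlation), although edgeR called 0 of the 28, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. This depended on the libraries that stand apart, and without the 3 all 28 fell. PRC1, a spindle midzone protein, went from -0.75 (adjusted p = 0.245) to -1.40 (adjusted p = 1.44e-09), and to -1.66 (adjusted p = 1.82e-06) without MCF-7 4-OHT replicate 5 alone. Estrogen receptor targets had 5 of 36 higher and 14 lower (8 and 19 adjusted over the list alone), at adjusted p = 0.0314, and adjusted p = 0.899 with an estimated correlation. PRSS23 (-1.36) and SGK3 (-1.21) fell, whereas RAPGEFL1 (1.73) and ADORA1 (2.95), also estrogen-regulated, rose. The call of this list was lost without MCF-7 4-OHT replicates 4 (adjusted p = 0.0829) or 5 (adjusted p = 0.167), and its direction turned without MCF-7 DMSO replicate 5 (adjusted p = 0.658).

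Luminal markers rose in MCF-7, 7 of 22 with 0 lower in both adjustments (adjusted p = 0.000146, and adjusted p = 0.00487 with an estimated correlation), with ELF3 at 1.18, MUC1 at 1.11 and the pioneer factor FOXA1 at 0.60. Aryl hydrocarbon receptor and xenobiotic genes had 4 of 18 higher and 0 lower (5 and 1 adjusted over the list alone), at adjusted p = 4.91e-05 and adjusted p = 0.00233 with an estimated correlation. The members that rose included the steroid glucuronidating enzymes UGT2B15 (2.12) and UGT2B17 (2.41, and 3.15 without MCF-7 DMSO replicate 5), whose near-identical sequences make the split of reads between them uncertain. Respiratory chain genes shifted down, 2 of 36 lower (1 adjusted over the list alone), at adjusted p = 0.000615, and adjusted p = 0.899 with an estimated correlation. That call was lost without MCF-7 DMSO replicate 2 (adjusted p = 0.0941). Its member COX6C (-1.70, adjusted p = 0.0185) lost its call without MCF-7 DMSO replicate 5 (-1.04, adjusted p = 0.0582) or any of MCF-7 4-OHT replicates 1 to 4 (adjusted p = 0.0512 to 0.0601).

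**Figure D4:**
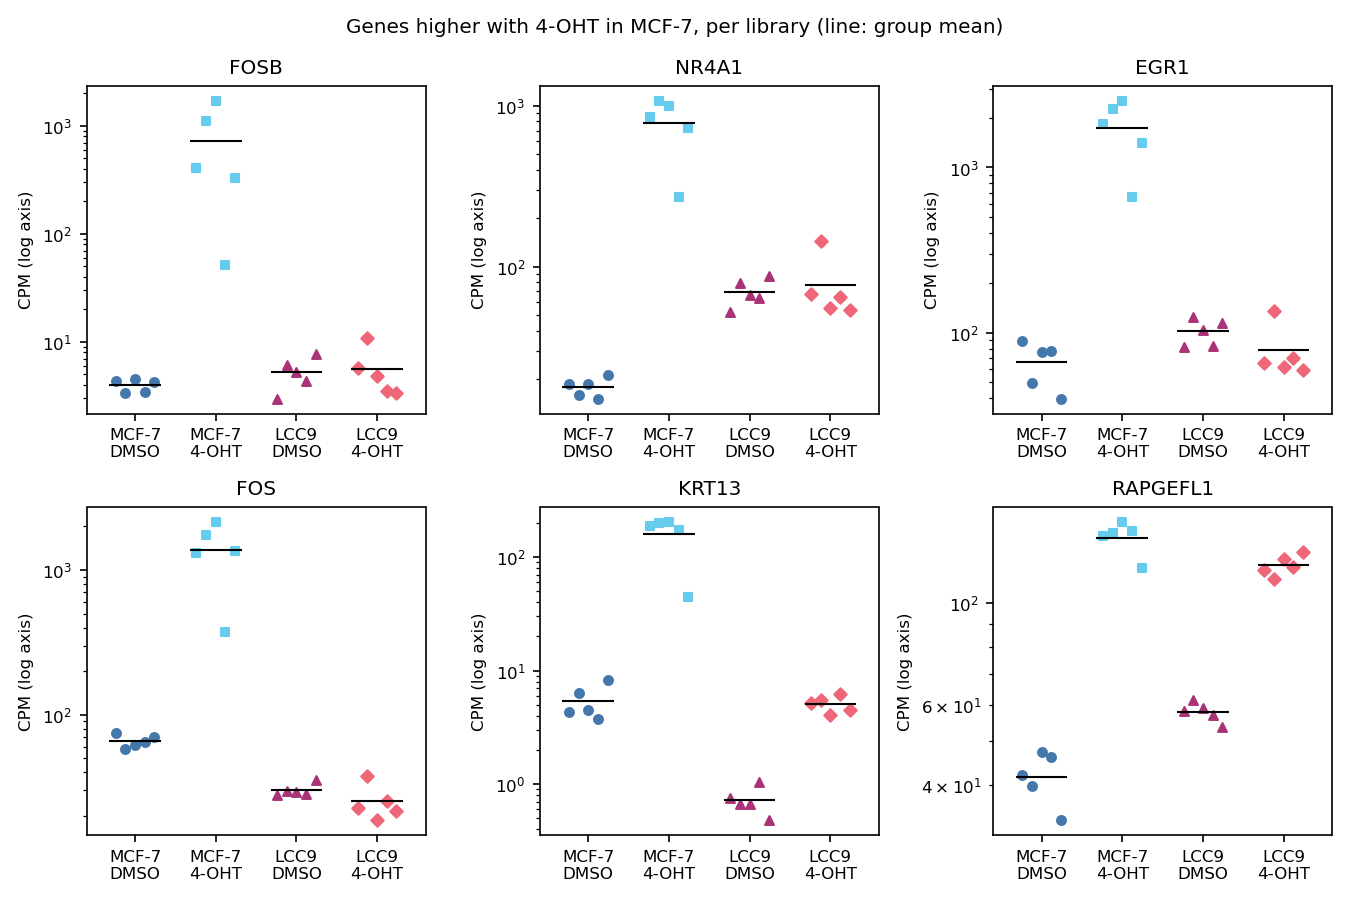
Points give each library's CPM on a log axis for 4 immediate early genes and for KRT13 and RAPGEFL1, by group, with lines at group means. FOSB lay between 51 and 1700 CPM in the MCF-7 4-OHT libraries and at 10.9 or less in every other library.

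In LCC9, the comparison of 4-OHT with DMSO asked what the drug still did in the resistant line. A small set of genes rose from low levels. ATP4A, which encodes the gastric proton pump, went from 0.425 ± 0.178 to 16.1 ± 1.59 CPM (log2 5.23 ± 0.29, adjusted p = 7.48e-10; chromosome 19, 35550043 to 35563658), the kinase FGR from 0.34 ± 0.0884 to 5.45 ± 0.317 (3.97 ± 0.23), and SERPINA1, alpha-1 antitrypsin, from 8.99 ± 1.06 to 48.8 ± 2.66 (2.44 ± 0.23; chromosome 14, 94376747 to 94390693). TFF1 (0.62 ± 0.28, adjusted p = 0.512), GREB1 (0.49 ± 0.42, adjusted p = 0.767), PGR (0.99 ± 0.34, adjusted p = 0.244) and ESR1 (-0.06 ± 0.17, adjusted p = 0.943) did not pass the test. Without the 3 MCF-7 libraries, which enter through the shared estimate of the spread, TFF1, GREB1 and PGR passed (adjusted p = 0.00698, 0.0335 and 0.000604), PGR also without MCF-7 DMSO replicate 5 alone (adjusted p = 0.0219).

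The other highest genes were SERPINA6, the corticosteroid-binding globulin gene neighbouring SERPINA1 (log2 3.95), INHBE (3.04), KRT13 (2.79), PITX1-AS1 (2.61), TGM2 (2.45), MAG (2.23) and the prostaglandin transporter SLCO2A1 (2.14), with a largest adjusted p of 0.015. The lowest genes included DEPP1 (-1.13), KIF23-AS1 (-1.12), the dopamine receptor DRD1 (-1.01), CITED4 (-1.0), the cholesterol-esterifying SOAT2 (-0.99), ARRDC4 (-0.99), SERHL2 (-0.94), SOX18 (-0.86) and FBXO10 (-0.80). Leaving out single libraries ended the calls of KIF23-AS1 in 16, SERHL2 in 8, DEPP1 and SOAT2 in 7 each, DRD1 in 6, INHBE in 3 and TGM2 in 2 of 20 fits, and antisense genes carry the doubt named for TM4SF18-AS1.

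The drug changed 161 genes in LCC9 (0.94%), 130 up and 31 down, with a median absolute log2 change of 0.994, and 1464 without the 3 MCF-7 libraries (771 up, 693 down). Fitted on the 2 LCC9 groups alone, the count was 694 (421 up, 273 down), above the 360 of such a fit in MCF-7. So whether the drug changed fewer genes in LCC9 depended on the fit. DESeq2 gave 383 genes, and removal of the transcript length trend 266. Across genes the fold change had a correlation of 0.385 with log2 transcript length. The count was 442, 245 and 255 without MCF-7 DMSO replicate 5, MCF-7 DMSO replicate 2 and MCF-7 4-OHT replicate 5. It was 97, 95, 103 and 92 without LCC9 DMSO replicates 1 and 5 and LCC9 4-OHT replicates 4 and 5.

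Genes of the unfolded protein and integrated stress response had 3 of 26 higher and 0 lower (12 and 0 adjusted over the list alone), at adjusted p = 3.32e-12 and adjusted p = 0.0494 with an estimated correlation. PSAT1, an enzyme of serine synthesis, rose by log2 1.07, the stress-induced SESN2 by 0.81 and the chaperone partner DNAJB9 by 0.43 (adjusted p = 0.0397, lost in 13 of 20 fits that left out a library). Estrogen receptor targets had 3 of 36 higher and 0 lower (10 and 1 adjusted over the list alone), at adjusted p = 3.18e-09 and adjusted p = 0.263 with an estimated correlation. They were RAPGEFL1 (1.07), CTSD (0.76, lost in 4 of the 20 fits) and RARA (0.59, lost in 15). The aryl hydrocarbon receptor and xenobiotic list had 1 of 18 higher (4 adjusted over the list alone), UGT2B15 at 1.32, with adjusted p = 0.00287 and adjusted p = 0.0408 with an estimated correlation. The NRF2 antioxidant list had 1 of 22 higher in both adjustments, the cystine transporter SLC7A11 at 1.58 (adjusted p = 0.0165, and adjusted p = 0.253 with an estimated correlation).

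Further lists shifted in LCC9 without a single member past the edgeR threshold over all genes. Basal and mesenchymal markers shifted up (median log2 0.281, adjusted p = 0.00407, and adjusted p = 0.0494 with an estimated correlation), with 1 of 18 adjusted over the list alone, 5 at an unadjusted p under 0.05 and 2 by DESeq2. TP63, a basal transcription factor, stood at 0.93 ± 0.23 with adjusted p = 0.063, which fell to 0.0266, 0.0179, 0.0431 and 0.0196 without MCF-7 DMSO replicates 2 and 5 and MCF-7 4-OHT replicates 3 and 5. The NF-kB and chemokine list shifted up (adjusted p = 0.0165, and adjusted p = 0.271 with an estimated correlation; 3 of 18 at an unadjusted p under 0.05, 1 by DESeq2), and its call was lost without LCC9 DMSO replicates 2 (adjusted p = 0.0608) or 3 (0.0575) or LCC9 4-OHT replicate 2 (0.0818). Further down shifts were those of DNA replication (adjusted p = 0.00068, 3 of 29 at an unadjusted p under 0.05), the respiratory chain (adjusted p = 0.00691, 1 of 36) and interferon-stimulated genes (adjusted p = 0.0337, 5 of 41), with 0 by DESeq2 in each and adjusted p = 0.813 for each with an estimated correlation. The interferon call was lost without LCC9 DMSO replicates 2 (adjusted p = 0.0604) or 4 (0.088) or LCC9 4-OHT replicates 1 (0.104) or 3 (0.101). The respiratory chain call was lost without LCC9 DMSO replicate 1 (0.133) or LCC9 4-OHT replicates 3 (0.101) or 5 (0.0731).

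Whether the drug acted differently in the lines was tested directly, as the difference of the 4-OHT effects, LCC9 minus MCF-7. The rise of immediate early genes from the DMSO to the 4-OHT libraries was far larger in MCF-7 than in LCC9, although the labels do not separate the drug from handling shared by the treated cultures. The effects on the estrogen-induced GREB1 and TFF1 differed. Among genes with a mean count of at least 10 in each group, the 6 lowest differences were FOSB (log2 -7.40 ± 0.87, adjusted p = 3.38e-05), CCN2 (-5.83 ± 0.55), NR4A1 (-5.31 ± 0.44), EGR1 (-5.08 ± 0.45), EGR2 (-4.78 ± 0.74) and FOS (-4.65 ± 0.42). The 6 highest, under the same limit, were PKDCC (6.17 ± 1.5), GREB1 (4.67 ± 0.62, adjusted p = 0.000133), CHAC1 (3.02 ± 0.78), TFF1 (2.81 ± 0.41, adjusted p = 0.000344), TFF3 (2.72 ± 0.43) and the stress gene NUPR1 (2.71 ± 0.49). MCF-7 DMSO replicate 5 weighed on several: without it PKDCC differed by 1.62, CHAC1 by 1.48 and GREB1 by 3.71, each past the threshold. Leaving out other libraries ended the calls of PKDCC in 12 and CHAC1 in 14 of 20 fits. PGR differed by 1.84 (adjusted p = 0.0493, lost in 17 of the 20 fits) and ESR1 by 0.24 (adjusted p = 0.798; 0.57 with adjusted p = 0.0348 without the 3 libraries).

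In all, 375 genes (2.19%) differed in their response, 152 more positive and 223 more negative in LCC9, with a median absolute difference of log2 1.10, and 1901 without the 3 libraries (990 and 911). A wrong split of the same libraries gave 611 calls, so this count does not by itself show a different response to the drug. Scaling by library sizes alone gave 205 and 180. DESeq2 gave 649 genes (310 and 339), and removal of the transcript length trend 628 (274 and 354). The count was 712 without MCF-7 DMSO replicate 5 and 1014 without MCF-7 4-OHT replicate 5. Immediate early genes had 14 of 24 more negative and 0 more positive (19 and 1 adjusted over the list alone), at adjusted p = 2.11e-61 and adjusted p = 0.000575 with an estimated correlation. Luminal markers had 4 of 22 more negative, among them ELF3 (-1.55) and MUC1 (-0.95), with 5 adjusted over the list alone (adjusted p = 0.000114, and adjusted p = 0.00578 with an estimated correlation). On the positive side, replication genes had 4 of 29 (12 adjusted over the list alone), with MCM2 at 1.03 and MCM6 at 0.83, and adjusted p = 3.22e-18. Estrogen receptor targets had 6 of 36 and 2 negative (20 and 3 adjusted over the list alone), with SGK3 at 1.36 and PRSS23 at 1.29, and adjusted p = 5.92e-11. The stress response list had 4 of 26 and 1 negative (12 and 2 adjusted over the list alone), with TRIB3 at 1.11, DDIT4 at 1.04 and PPP1R15A at -1.24, and adjusted p = 1.35e-05. All of these last 3 lists had adjusted p = 0.26 with an estimated correlation. Mitosis genes shifted up (median log2 0.358, adjusted p = 0.000357, and adjusted p = 0.919 with an estimated correlation) with 0 of 28 called by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2, and all 28 were called more positive without the 3 libraries.

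Some of the response was common to the lines. Of the genes called in both, 47 rose in both, where independent lists would share 5.13 (one-sided Fisher's exact test, p = 6.49e-33), and 8 fell in both, against 1.16 (p = 1.32e-05). Another 3 rose in MCF-7 and fell in LCC9 and 7 did the reverse, against 1.22 and 4.85. The test takes genes as independent, which they are not. It also ignores that the drug effects in both lines correlated with log2 transcript length (0.304 in MCF-7, 0.385 in LCC9). Of the 161 genes called in LCC9, 114 moved the same way in MCF-7, and of the 1315 called in MCF-7, 884 moved the same way in LCC9. The median ratio of the LCC9 to the MCF-7 effect was 0.139 over the MCF-7 calls and 0.721 over genes called in both, and the effects had a correlation of 0.172 across all tested genes. The overlap of 55 genes became 411 without the 3 libraries. It was 122 and 91 without MCF-7 DMSO replicate 5 and MCF-7 4-OHT replicate 5, and 32, 34, 35, 34 and 32 without LCC9 DMSO replicates 1, 4 and 5 and LCC9 4-OHT replicates 4 and 5.

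The design also allows the question whether LCC9 at baseline resembled drug-treated MCF-7. Genes higher in LCC9 tended to be those that 4-OHT lowered in MCF-7: 361 were higher in LCC9 and lowered by the drug, where independent lists would share 233, and 360 were lower in LCC9 and raised, against 255. Only 175 were higher and raised, against 246, and 118 lower and lowered, against 241. Both contrasts use the MCF-7 DMSO libraries. With those split between the contrasts, the covariance of log2 changes over genes was -0.23 ± 0.028 (SD over 10 splits) and the correlation -0.255. Unsplit, the covariance was -0.175 and the correlation -0.237. In 20 simulations of unchanged groups they were 0.0283 and 0.501 unsplit and 0.000121 and 0.00143 split, so the unsplit covariance lay -0.203 from its simulated value. Without MCF-7 DMSO replicate 5 the split covariance was -0.123, and without the 3 libraries -0.0948 over 3 splits, with a correlation of -0.113. With each library's trend on transcript length removed it was -0.21 with all libraries and -0.0927 without the 3.

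Because the series was made to accompany a study of N6-methyladenosine (m6A), the commonest internal mark of mRNA, the proteins that write, erase and read the mark were examined as a list fixed beforehand. YTHDF1, a reader of the mark, was lower in LCC9, at 68.3 ± 3.0 against 184 ± 3.25 CPM in DMSO (log2 -1.43 ± 0.06, adjusted p = 4.36e-14; chromosome 20, 63195429 to 63216234) and by -1.42 in 4-OHT. The nuclear reader YTHDC1 (-0.93), the catalytic writer METTL3 (-0.53) and the eraser ALKBH5 (-0.47) were lower in DMSO as well. Higher in LCC9 were the reader IGF2BP2, at 13 ± 2.38 against 2.24 ± 1.94 CPM (2.56 ± 0.37; 3.22 without MCF-7 DMSO replicate 5), the ribosomal RNA writer METTL5 (1.48), the writer complex scaffold WTAP (0.85) and the ribosomal RNA writer ZCCHC4 (0.80). In 4-OHT, IGF2BP2 (4.11), METTL5 (1.76) and WTAP (1.04) were again higher. METTL14, the partner of METTL3, changed by 0.08 (adjusted p = 0.465) and the eraser FTO by 0.10 (adjusted p = 0.771). FTO held 81.5 CPM in MCF-7 DMSO replicate 5 and 13.4 to 23.8 in the other libraries of the group and was called at 0.78 (adjusted p = 3.21e-05) without it. HNRNPA2B1 was called at -0.75, but with the transcript length trend of each library removed its change was -0.32 (adjusted p = 0.0935), while METTL14 (0.55) and FTO (0.88) passed.

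In DMSO, 4 of 26 genes of the m6A list were higher in LCC9 and 14 lower, also adjusted over the list alone, and the list as a whole did not stand apart from the other genes (adjusted p = 0.396). In 4-OHT 6 were higher and 15 lower (adjusted p = 0.484). The drug itself changed 1 of the 26 in MCF-7 (0 adjusted over the list alone), IGF2BP2 at -1.44 (adjusted p = 0.0368), whose call was lost without MCF-7 DMSO replicate 5 (adjusted p = 0.111) or MCF-7 4-OHT replicates 1 (0.0518), 2 (0.104) or 4 (0.0954). None of the 26 was called in LCC9, where 0 had an unadjusted p under 0.05 by edgeR and 0 were called by DESeq2, and the list tests gave adjusted p = 0.765 in MCF-7, 0.887 in LCC9 and 0.789 for the difference.

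**Figure D5:**
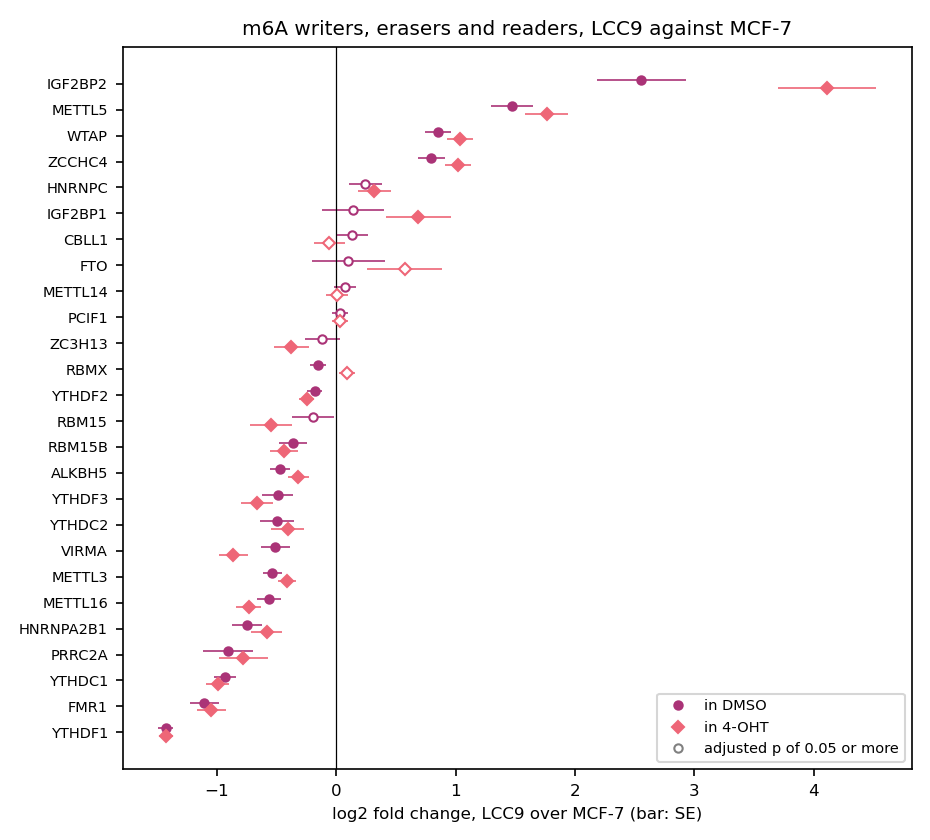
Points give the log2 fold change of LCC9 over MCF-7 for 26 genes of the m6A list, in DMSO (circles) and in 4-OHT (diamonds), with bars of 1 SE; open symbols mark an adjusted p of 0.05 or more. YTHDF1 lies lowest, at -1.43 and -1.42, and IGF2BP2 highest, at 2.56 and 4.11.

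Markers of cell types that a culture of these lines should lack were mostly untested for want of counts, and none of their lists was called. Of 18 immune markers 5 were tested, with 3 higher and 1 lower in LCC9 in DMSO (adjusted p = 0.0743): CD8A rose from 1.07 ± 0.415 to 21.2 ± 1.90 CPM, and CD19 stood at 3.30 ± 1.20 CPM in LCC9, at least 168-fold above MCF-7, which had no count. Fibroblast markers were tested in 7 cases, with 3 higher and 4 lower in 4-OHT (smallest adjusted p = 0.45). In DMSO the collagen gene COL3A1 fell from 58.5 ± 82.7 to 0.0508 ± 0.0183 CPM (log2 -10.07, and -8.63 without MCF-7 DMSO replicate 5, which held 206 CPM), FBLN1 fell by 8.09 (8.92 without LCC9 DMSO replicate 1) and ACTA2 rose by 1.84. Endothelial markers (5 tested) and blood and liver markers (3 tested) had smallest adjusted p of 0.146 and 0.152. Yet 2 of the 3 blood and liver markers were higher in LCC9 in DMSO and 3 in 4-OHT, with 0 lower. Of the endothelial markers 2 were higher and 1 lower in LCC9 in DMSO, and 2 higher and 2 lower in 4-OHT. The remaining lists fixed beforehand were called in no comparison, with smallest adjusted p of 0.329 for sterol synthesis, 0.277 for fatty acid synthesis, 0.421 for glycolysis and hypoxia, 0.329 for the BCL2 family and 0.236 for p53 targets.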

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

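Of the tests in this part, those of a mixture with LCC9, of handling in both its forms, of GC content and of depth were chosen only after the result was seen.

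MCF-7 DMSO replicate 5 stood at 7.36 in the mean log2 CPM of the 36 estrogen receptor targets, where the other 4 libraries of its group lay between 5.77 and 5.80, a gap of 0.981 of the group's range against Dixon's critical value of 0.71. A mixture with LCC9 cells or RNA was excluded by genes at 20 CPM or more in LCC9 DMSO and at 0.1 CPM or less in the other 4 libraries: the 21 genes reached a median of 0.132% of the LCC9 level in replicate 5, and 19 of them stayed under 2%. Of the targets, 22 stood at least 2-fold above the other libraries and 0 as far below, but higher estrogen receptor activity stays open, as this list is the one that showed the pattern and so gives no test of it. Regional copy-number differences stay open, because deviations of neighbouring genes had a correlation of 0.221, between the values set for and against them, and MCF-7 DMSO replicate 1 had 0.387. Whether this culture met other medium or other hormone levels was not tested.

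The 19 immediate early genes that rose with 4-OHT in MCF-7 had a mean log2 CPM of at least 6.49 in each treated library and of at most 4.84 in each DMSO library. Many genes of this class respond within minutes to fresh serum or to handling. Handling that differed from culture to culture stays open. Over these genes the treated libraries spread 1.08 times as widely as over the 69 other genes raised at least 4-fold. That ratio was under the 1.5 set for it (median SD 0.576 and 0.534 on the log2 scale). It cannot decide, because the 69 genes were raised in the same libraries, and some, such as KRT13, stood far lower in MCF-7 4-OHT replicate 5. Handling shared by the treated MCF-7 cultures and an effect of the drug cannot be told apart, because 0 of the MCF-7 DMSO libraries reached the lowest treated score and the same 5 libraries carry both. The labels give no harvest order that could separate them.

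Within each treatment the LCC9 libraries fell into 2 sets, DMSO replicates 2 and 3 with 4-OHT replicates 3 and 5 against the other 6, along a component that held 75.7% of the variance of their deviations from the group means. Transcript length bias between libraries has the values it needs: deviations correlated with log2 transcript length over 10239 genes at 0.544 to 0.675 in the first set and at -0.606 to -0.405 in the second, so the smallest absolute r was 0.405. GC content alone did not separate the sets. Correlations of the deviations with it were -0.197 to -0.021 in the first set and -0.213 to 0.408 in the second. In the second set, 2 libraries lay at or below the highest of the first. A part of GC content stays open, because this overlap cannot exclude it. Depth was argued against, as the library of the first set had the higher total in 50% of the pairs between the sets. The sets are no groups of the study, so no biological explanation was tested. Deviations of MCF-7 libraries followed transcript length as well. Of the 3 libraries that stand apart, MCF-7 DMSO replicate 2 had a correlation of -0.696 and MCF-7 4-OHT replicate 5 of -0.391, but MCF-7 DMSO replicate 5 of -0.0327. The other MCF-7 DMSO libraries had 0.487 to 0.583, and MCF-7 4-OHT replicates 1 to 4 had -0.0885 to 0.528.

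Other splits of the same libraries were counted for each comparison, 100 of 126 possible ones (31752 for the difference of drug effects), the real split included. For the lines in DMSO, 1 of the 100 gave as many calls as the real 12706, namely the real one, and the highest other gave 7755. For the lines in 4-OHT that number was 1, with 13233 calls and a highest other of 5679, and for the drug in LCC9 it was 1, with 161 calls and a highest other of 1. For the drug in MCF-7, 4 of the 100 gave at least the real 1315, with others at 2681, 2338 and 2262. The highest of them set MCF-7 DMSO replicate 1 with 4-OHT replicates 1 to 4, so that the 3 libraries that stand apart fell on the other side, which points to a structure of the samples beside the treatment. For the difference of drug effects 2 of the 100 reached the real 375, the other at 611 with MCF-7 DMSO replicate 3 beside 4-OHT replicates 1 to 4, and the next gave 204. For both line comparisons and the drug in LCC9 only the real split reached the real count, a share under the bound of 0.05. This argues against an arbitrary division of these libraries as the source of those counts. It cannot exclude a chance difference between cultures or batches, since the labels do not show separate cultures. The shares for the drug in MCF-7 and for the difference were also under the bound of 0.05. Yet wrong splits gave more calls than the real one in both. These shares therefore neither exclude chance nor show that the treatment made those counts.

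Single libraries stood far from the rest of their group for 60 of the 383 pairs of a named gene and a group, by the gap to the nearest library over the group's range of log2 CPM, where chance gives about 1 in 20. In MCF-7 DMSO replicate 5 the high genes were MAP1LC3B2 (0.928), COL3A1 (0.925), CHAC1 (0.925), PKDCC (0.909), TNS4 (0.884), AREG (0.845), PRC1 (0.835), ASS1 (0.817), PLCXD3 (0.783), PHGDH (0.782), PADI3 (0.764), AFAP1L2 (0.76), FBLN1 (0.76), CDCA7 (0.76) and ZCCHC4 (0.729). Its low genes were CCN2 (0.901), KCNJ8 (0.872), HPGD (0.861), TGM2 (0.767) and FLRT3 (0.745). In MCF-7 4-OHT replicate 5 the estrogen-induced TFF1 (0.962) and TFF3 (0.904) and the cell cycle genes PRC1 (0.874), MCM7 (0.833) and MCM2 (0.828) stood high, as did PCDH10 (0.87), COX6C (0.848) and RGS22 (0.802). Low there were KRT13 (0.899), TGM2 (0.886), ADORA1 (0.877), FLRT3 (0.863), ARMCX1 (0.78), TMEM26 (0.748), GREB1 (0.741), CLEC3A (0.732), RAPGEFL1 (0.72) and BTNL9 (0.717). In MCF-7 DMSO replicate 2, AGR2 (0.821), MCM7 (0.798), PPP1R15A (0.792), HOXB7 (0.773) and KREMEN2 (0.757) stood high and CLEC3A (0.785) low.

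The remaining single libraries were fewer. LCC9 DMSO replicate 4 stood high for SOX18 (0.777) and PADI3 (0.773) and low for MCM2 (0.72) and MCM6 (0.715). LCC9 DMSO replicate 5 stood high for CCN2 (0.852) and FOS (0.767), and LCC9 4-OHT replicate 2 for EGR1 (0.794) and NR4A1 (0.777). SERPINA6 was low in LCC9 4-OHT replicate 1 (0.829), IL22RA1 in LCC9 DMSO replicate 1 (0.788), SLC22A4 in MCF-7 4-OHT replicate 2 (0.803) and CAV1 in MCF-7 DMSO replicate 3 (0.805). MCF-7 4-OHT replicate 4 was high for YTHDF1 (0.725) and low for NR4A1 (0.721) and FOS (0.715).

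The effect of 4-OHT differed between the lines, by edgeR's test of the difference itself, for 375 genes in all. Those of them that the report names for the drug were partly picked by this test. Below MCF-7 by log2 lay FOSB (-7.40), CCN2 (-5.83), NR4A1 (-5.31), EGR1 (-5.08), EGR2 (-4.78), FOS (-4.65), DUSP1 (-3.74), RASD1 (-3.49), FCGR2B (-2.68), KIF23-AS1 (-2.38), KRT13 (-2.11), ADORA1 (-2.09), DRD1 (-1.94), DEPP1 (-1.75), ELF3 (-1.55), ARRDC4 (-1.27), PPP1R15A (-1.24), MUC1 (-0.95), UGT2B15 (-0.80) and RAPGEFL1 (-0.67). Above MCF-7 lay PKDCC (6.17), INHBE (5.84), GREB1 (4.67), CHAC1 (3.02), TFF1 (2.81), TFF3 (2.72), NUPR1 (2.71), PGR (1.84), PITX1-AS1 (1.83), RGS22 (1.77), CDCA7 (1.71), SLC7A11 (1.71), TP63 (1.59), KREMEN2 (1.55), SGK3 (1.36), PRSS23 (1.29), TRIB3 (1.11), DDIT4 (1.04), MCM2 (1.03), SESN2 (0.90), MCM6 (0.83) and MCM7 (0.66). Among lists the difference passed for immediate early genes (adjusted p = 2.11e-61), DNA replication (3.22e-18), estrogen receptor targets (5.92e-11), the stress response (1.35e-05), luminal markers (0.000114) and mitosis (0.000357). With an estimated correlation it passed for immediate early genes (adjusted p = 0.000575) and luminal markers (0.00578) only, with 0.26 for DNA replication, estrogen receptor targets and the stress response each and 0.919 for mitosis.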

How the results depend on the processing

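Of the alternatives below, the fits without the 3 MCF-7 libraries that stand apart and those with the transcript length trend removed were chosen only after the result was seen. Scaling, the CPM filter and a robust spread left each of the 5 counts within 1.5 times its value. A 2-fold threshold gave 6569, 7379, 425, 80 and 208 genes for the lines in DMSO, the lines in 4-OHT, the drug in MCF-7, the drug in LCC9 and the difference, with overlaps of 28 for the drug and 5975 for the lines, since it can only remove calls. For the same reason an adjusted p under 0.01 gave 573 and 75 genes for the drug in MCF-7 and LCC9, 166 for the difference and an overlap of 27. With only the libraries compared, the drug called 360 genes in MCF-7 (253 higher, 107 lower, 70.3% higher) and 694 in LCC9. The order of the lines thus turned. These fits take the spread, the filter and the scaling from the compared groups alone, and which of these moved the counts was not tested. DESeq2 gave 383 for the drug in LCC9, 649 for the difference and an overlap of 95, and the length trend removed gave 266 and 628 for the first pair of these, and the cause was not tested. Without the 3 libraries the drug called 2819 and 1464 genes, the difference 1901 and the overlap 411, and the covariance of the LCC9 baseline and the drug effect in MCF-7 was -0.0948, against -0.132 with no low-count filter. Leaving out single libraries gave 12265 to 13185 genes for the lines in DMSO, 12822 to 13708 for the lines in 4-OHT, 761 to 2804 and 92 to 442 for the drug in MCF-7 and LCC9, 263 to 1014 for the difference, overlaps of 32 to 122 for the drug and 11316 to 12126 for the lines, and a covariance of -0.29 to -0.123. Of 39 list results, an estimated correlation left 16 on their side of the threshold and ended 23 calls, and fry left 22, ended 12 and added 5. Leaving out libraries left 765 of 780 list results in place, ended 13 calls, added 1 and turned 1, the estrogen receptor list for the drug in MCF-7 without MCF-7 DMSO replicate 5 (adjusted p = 0.658, over a range from 0.00176); the cause was not tested. Without the 3 libraries that list (adjusted p = 0.701) and the respiratory chain list (adjusted p = 0.0769) lost their calls for the drug in MCF-7. For the 191 gene results, leaving out libraries left 3668 of 3820 in place, ended 142 calls and added 10. DESeq2 left 178 of 180, adding TP63 and ending INHBE (adjusted p = 0.0903), the length trend removed left 182, added 7 and ended 2, and no low-count filter left 188 and ended 3. DESeq2 size factors and library sizes alone each ended 1. At the depth, spread and number of libraries here, a simulated log2 change of 0.5 was recovered in the drug comparison in MCF-7 for 18.6% of changed genes.

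With replicate number as a block the counts were 12588, 13155, 1122, 134 and 300. Of 30 pairs with the same number, 13 had deviations correlated above 0.1, over a range of -0.572 to 0.441. In every other group together, 0 libraries correlated best with their own number, so the numbers gave no general pairing. Pairing of some libraries is not excluded. MCF-7 DMSO replicate 5 correlated at 0.219 with MCF-7 4-OHT replicate 5 and negatively with the other treated MCF-7 libraries. The block changed no call of a list and left 181 of 191 gene results in place, ending 9 calls and adding the call of GREB1 for the lines in DMSO (adjusted p = 0.0452).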

Other observations

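The gene groups in this part were chosen only after the result was seen, and their tests are of genes picked in the same data.

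LCC9 carried mRNA of cytokines of the interleukin-10 family that MCF-7 hardly held. IL20 stood at 528 ± 50.1 CPM in LCC9 DMSO and 0.0336 in MCF-7 DMSO (log2 13.80). Its chromosome 1 neighbour IL24 stood at 125 ± 12.6 CPM and had 2 counts over the 5 MCF-7 DMSO libraries, and IL19, of the same cluster, stood at 16.3 ± 2.46 and 0.0257 CPM (9.07). Receptor genes of these cytokines, IL20RA (3.08) and IL22RA1 (2.39), were higher too, so that 5 of 7 tested members rose and 0 fell. As IL20, IL24 and IL19 were nearly absent from MCF-7 DMSO, the filter favoured their rise in LCC9, and no test of this list is given. In LCC9, 4-OHT raised IL24 further by log2 0.80 (edgeR adjusted p = 0.00218), to 218 ± 31.9 CPM. Cancer-testis antigens of the X chromosome, genes mostly limited to germ cells, had 4 of 36 members with enough counts to be tested, which they reached in LCC9 alone, so that their direction was set by the filter and no list test is given. They were SAGE1 and 3 CT45A genes, near-identical copies among which counting can split reads.

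Homeobox genes, which set positional identity in development, differed by cluster. In LCC9 DMSO 6 of 8 tested HOXC genes were higher and 1 lower (camera adjusted p = 9.29e-09, and adjusted p = 0.00112 with an estimated correlation). HOXC10 rose from 2.73 ± 0.431 to 198 ± 13 CPM and HOXC4 from 3.82 ± 0.364 to 85.5 ± 7.0 CPM. HOXC9, located between them, fell by 1.30 on the log2 scale. All 7 tested HOXB genes were higher (adjusted p = 0.00123, and adjusted p = 0.02 with an estimated correlation), such as HOXB2 (log2 4.16), HOXB4 (4.72) and HOXB7 (1.11). Of 9 tested HOXA genes 1 was higher and 4 lower (adjusted p = 0.0945), with HOXA10 at -7.12. Of the HOXD cluster 2 genes were tested and 1 was higher, too few for a list test. Serine synthesis genes differed as well: PSAT1 stood at 35.3 ± 7.61 CPM in LCC9 DMSO and 0.0273 in MCF-7, and PHGDH, the first enzyme of the pathway, was higher by log2 2.67, or 4.21 without the 3 libraries that stand apart. The list of amino acid transport and serine synthesis genes had 9 of 15 higher and 2 lower in DMSO (adjusted p = 0.0421, and adjusted p = 0.42 with an estimated correlation), and 13 higher without MCF-7 DMSO replicate 5. In LCC9 4-OHT raised 3 of the 15 and lowered 0 (adjusted p = 3.36e-15, and adjusted p = 0.0379 with an estimated correlation; 11 raised without MCF-7 DMSO replicate 5), in MCF-7 it lowered 2 and raised 0 (adjusted p = 0.018, and adjusted p = 0.6 with an estimated correlation). The call of the list in MCF-7 rested on MCF-7 DMSO replicate 5 and was lost without it (adjusted p = 0.497, 1 lower). That library held 1920 CPM of SLC7A5, which was 1 of the lowered genes, and the others of its group held 21.6 to 26.6. Without it SLC7A5 changed by 0.26 (adjusted p = 0.506). The difference of these effects passed for 5 genes (adjusted p = 6.29e-14, and adjusted p = 0.0563 with an estimated correlation), and without that library for 7 (adjusted p = 2.36e-15, and adjusted p = 0.000809 with an estimated correlation).

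Line differences clustered along chromosomes. Over 446 windows of 25 neighbouring genes, 22 had a median log2 difference beyond 0.8 in size between LCC9 and MCF-7 in DMSO, 18 of them lower in LCC9, while 100 random gene orders gave at most 3 such windows. The lowest, at chromosome 20 from 62231922 to 63707465, had a median of -1.44 (-1.33 in 4-OHT) and 0 of 25 genes higher, and it holds YTHDF1, whose own change was -1.43. Of 142 tested genes of chromosome 20 from 48 Mb onward, 109 were lower and 14 higher, with a median of -1.06. As this region was chosen after the result was seen and holds the lowest window, no test of it is given. The next lowest window, at chromosome 4 from 53285 to 2041993, had a median of -1.25 but was mixed, with 10 of 25 genes higher in LCC9. The highest, at chromosome 4 from 169729465 to 184694618 and at chromosome 11 from 2928273 to 7513298, had medians of 1.05 and 1.04, little beyond the highest absolute median of 1.01 over the random gene orders. DNA copy number was not analysed here.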
